A study of Mus musculus with 11 samples.

How the data were processed

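Chromatin from adult male mouse testis was crosslinked, sonicated and immunoprecipitated with antibodies to DMC1 or RAD51 or with control IgG, per the labels' protocols. Library fragments of 150 to 250 bp were selected after amplification. Per the labels' protocols, the library preparation was changed in some samples. In the Klenow exo(-) libraries this enzyme alone did the end repair, for 1 h at 37 °C, in 1 of them followed by 2 h at 20 °C and an overnight step at 12 °C. In the KE libraries the DNA was denatured and quickly renatured before adapter ligation. Reads were placed on mouse build mm9 and the tool named is BWA, without a version, per the submitters' processing notes. How the fragments were sorted into classes is not given in the sources used here.

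The authors deposited 3 lists of fragments per library, 33 in all, for dsDNA, ssDNA type 1 and ssDNA type 2. Each line gives the position and strand of 1 fragment, a pair of whole numbers and a deposited score between 0 and 1000 of undocumented meaning. In the lists, dsDNA fragments have both numbers at 2 or less and ssDNA fragments have a first number of at least 6. A first number of 3 to 5 occurs in no list, so a share of ssDNA here is a share of the deposited classes and not of all sequenced fragments. Repeated lines were present and made up 4.51% to 42.2% of type 1 lines. Fragments with the same chromosome, start, end and strand were counted once. Such repeats need not be copies of 1 molecule, because identical type 1 fragments also occur in separately made libraries. The score was used only in an alternative. Type 1 fragments with a score of 0 made up 3.12% to 7.84% of a library.

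Hotspots were called in each library from midpoints of type 1 fragments in windows of 3000 bp (3 bins of 1000 bp) on chromosomes 1 to 19, X and Y. Each window was compared by an upper-tail Poisson test with the largest of the library mean, the mean of the surrounding 100 kb and the IgG KE library scaled by the type 1 totals. Windows with a Benjamini-Hochberg adjusted p of at most 0.01, at least 10 fragments and 3-fold enrichment were kept and merged. IgG KE itself was called without a control library. To avoid scoring a library on its own calls, Hop2 -/- and IgG libraries were scored on hotspots of unlabelled DMC1 KE, and the unlabelled DMC1 libraries on hotspots of Hop2 -/- DMC1 KE. The union of both sets was used for the sex chromosomes and for ratios per hotspot. The hotspot centre was the median midpoint in the library that called it, or in unlabelled DMC1 KE for the union. FPM are fragments per 1000000 type 1 fragments on these chromosomes. The median distance from centres was taken within 2.5 kb after subtracting the level between 2.5 and 5 kb.

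Shares carry Wilson 95% intervals, or exact binomial intervals for the sex chromosomes and for ratios of single hotspots. The 8 DMC1 and RAD51 libraries were tested by sign flips (256 in all). RAD51 against IgG was tested with limma 3.58.1 in R 4.3.3, with the intensity trend, on log2 of type 1 fragments plus 0.5, scaled to type 1 totals, with Benjamini-Hochberg adjustment at 0.05. Only RAD51 and IgG have replicates. Replicates 1 and 2 came from reciprocal crosses and so from different animals. The p-values measure the spread between these libraries, which includes any difference between the crosses. The labels do not say whether same-numbered RAD51 and IgG libraries share animals. With 2 against 2 libraries a permutation p cannot go below 0.333. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Single hotspots were named by a rule, the 10 with the highest FPM in each DMC1 KE library and the 10 highest and 10 lowest ratios between these libraries among hotspots with at least 100 fragments in them together. No genes were assigned, because the gene table at hand is of build GRCm38.p6.

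The calling was tested on simulated data, with hotspots planted on a background of 3900000 fragments, about the depth of Hop2 -/- DMC1 KE. It found 92.5% of 492 planted hotspots of 20 fragments and 100% of those of 50 or more. Of the 2080 called hotspots, 7.26% lay away from planted ones, and 2 libraries without hotspots gave 45 and 44. For RAD51 against IgG, simulated data with the real totals and 10644 hotspots had 50 hotspots changed at each size. The test found 1 of 50 with a log2 change of 1, 17 of 50 at 2, 41 of 50 at 3 and 43 of 50 at 4, with 2 calls among the 10444 unchanged. Simulated rates were means over the RAD51 and IgG libraries, for most hotspots above the real IgG rate. The spread was fixed and no library-wide shift was simulated, so these numbers need not hold for the real contrast.

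The alternatives chosen before the data were examined were repeats kept, type 1 and type 2 together, the other hotspot set, an adjusted p of 1e-05 in calling, calling without the IgG control, equal depth, a stricter overlap, other scalings, pseudocounts, filters and weights for RAD51 against IgG, each replicate left out, type 1 alone as ssDNA, and other counts for X. Fragments with a score above 0 only, and 3 other alternatives, were added after seeing the data. Fragments on chrM and unplaced contigs entered the ssDNA shares and not the hotspots.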

Results

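Adult mouse testis was profiled by a sequencing method that separates fragments derived from single-stranded DNA (ssDNA) from those derived from double-stranded DNA (dsDNA). During meiosis, programmed DNA breaks are resected to ssDNA, which the recombinases DMC1 and RAD51 coat, so chromatin immunoprecipitation of these proteins recovers the ssDNA around break hotspots. The 11 libraries fall into 9 groups, and 7 groups hold 1 library. The labels list Hop2 -/- mice, which lack a partner of DMC1 and RAD51 in strand exchange, for 8 libraries. These are DMC1 by the standard protocol, RAD51 (replicates 1 and 2) and control IgG (replicates 1 and 2) by the standard protocol, DMC1 with 2 versions of end repair by Klenow exo(-), and DMC1 by kinetic enrichment (KE), in which DNA was denatured and quickly renatured before adapter ligation. The other 3 libraries, DMC1 standard, DMC1 KE and IgG KE, carry no Hop2 genotype and are called unlabelled here. All mice were F1 hybrids of 9R and 13R, and the replicate 2 libraries came from the reciprocal cross. The libraries held between 1973988 (DMC1 Klenow exo(-), 12 °C) and 37130504 (RAD51 replicate 2) distinct fragments, each in 1 of 3 deposited classes, ssDNA type 1, ssDNA type 2 or dsDNA. Intervals below cover counting error only, and comparisons of groups with 1 library have no replicate check.

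The first comparison asked how much of each library was ssDNA. In Hop2 -/- testis by the standard protocol, ssDNA (types 1 and 2) made up 18.7% of the DMC1 library (Wilson 95% interval 18.7 to 18.7), 15.5% and 9.86% of the RAD51 libraries, and 3.24% and 2.93% of the IgG libraries. The RAD51 mean was 12.7% ± 3.996 (SD, n = 2) and the IgG mean 3.09% ± 0.223 (SD, n = 2), a difference of 9.60 percentage points. Both RAD51 values lay above both IgG values, and the exact two-sided permutation test gave p = 0.333, the smallest p that 2 against 2 libraries allow. The unlabelled DMC1 standard library held 5.72% ssDNA. After KE the shares were 95.6% for Hop2 -/- DMC1, 92.4% for unlabelled DMC1 and 59.7% for unlabelled IgG. Type 1 made up between 83.5% and 88.3% of the ssDNA in the DMC1 and RAD51 libraries except unlabelled DMC1 KE (79.1%), and 72.8%, 70.8% and 67.9% in the IgG libraries.

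**Figure D1:**
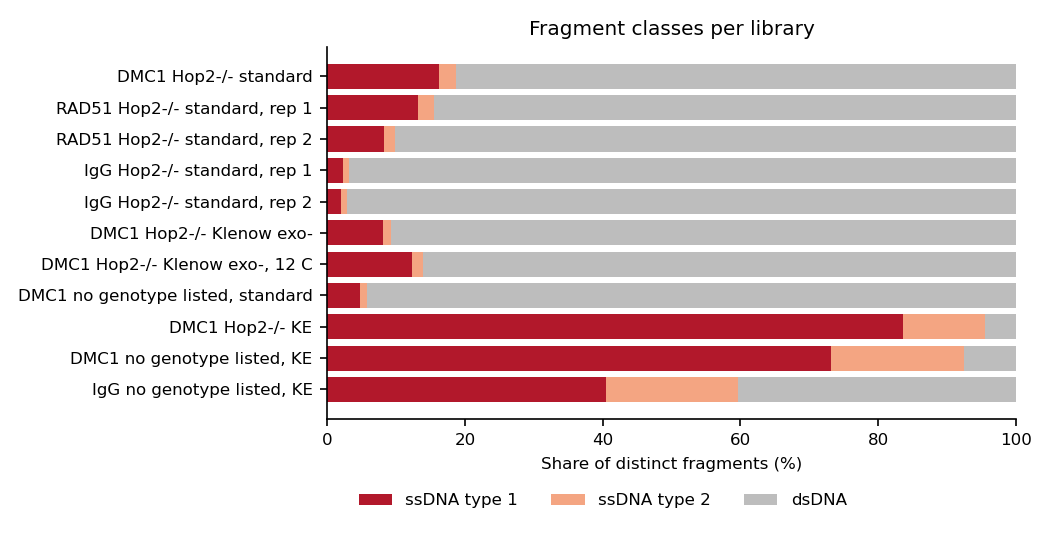
Share of distinct fragments in each class (%, horizontal axis) for the 11 libraries (vertical axis), as stacked bars of type 1 ssDNA, type 2 ssDNA and dsDNA. The KE libraries are mostly ssDNA, at 95.6%, 92.4% and 59.7%, while the 8 other libraries range from 2.93% to 18.7%.

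To locate the ssDNA, hotspots were called from type 1 fragments in each library. Hop2 -/- DMC1 gave 11365 hotspots by the standard protocol and 11549 by KE, RAD51 gave 8275 and 9759, and unlabelled DMC1 gave 2836 by the standard protocol and 10644 by KE. The Klenow exo(-) libraries gave 1998 and 1611. The control IgG libraries gave 360 and 8 hotspots by the standard protocol in Hop2 -/- and 231 by KE. With repeated fragments kept IgG KE gave 1091, and called without the IgG control IgG replicate 2 gave 20. In the Hop2 -/- KE set 11123 hotspots were autosomal and 421 lay on X outside its distal 300 kb, against 9868 and 763 in the unlabelled KE set. Hotspots had a median length of 6.0 kb in both sets and covered 66.9 and 59.6 Mb. The strongest 1154 hotspots of the Hop2 -/- KE set held 41.3% of its hotspot fragments, and the strongest 1064 of the unlabelled KE set held 38.2%. The counts depended on depth. With 140000 type 1 fragments drawn from each library, Hop2 -/- DMC1 standard gave 3211 hotspots, RAD51 2811 and 2091, Hop2 -/- DMC1 KE 2118, the Klenow exo(-) libraries 1232 and 838, unlabelled DMC1 KE 776, unlabelled DMC1 standard 366, and the IgG libraries 5, 7 and 9.

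The hotspot with the most type 1 fragments in both KE libraries lay at the distal end of X, at chromosome X, 166415001 to 166431000 (mm9). Hotspots were ranked by fragments over the whole called interval, which favours long ones. This interval was longer than the median hotspot, and no rank per kb was made. X and Y pair through the pseudoautosomal region at this end, and the boundary of that region was not placed here. The hotspot held 668 fragments per 1000000 type 1 fragments (FPM) in Hop2 -/- KE and 613 FPM in unlabelled KE, against 15.4 in IgG KE. It was also high in the standard libraries, at 1310 FPM in Hop2 -/- DMC1, 1478 and 1042 in RAD51 and 432 in unlabelled DMC1, against 82.5 and 26.9 in the Hop2 -/- IgG libraries. The other 9 of the 10 strongest Hop2 -/- KE hotspots were autosomal, led by chromosome 15, 91085001 to 91093000 (469 FPM in Hop2 -/- KE, 164 in unlabelled KE), chromosome 3, 81552001 to 81560000 (431 and 244), and chromosome 5, 81925001 to 81933000 (416 and 225). The other 9 of the 10 strongest unlabelled KE hotspots were all on X outside the distal 300 kb. They were led by 53608001 to 53619000 (211 FPM in Hop2 -/- KE, 533 in unlabelled KE), 39560001 to 39572000 (149 and 414) and 83993001 to 84001000 (173 and 376). Which genes lie in these regions was not analysed here.

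**Figure D2:**
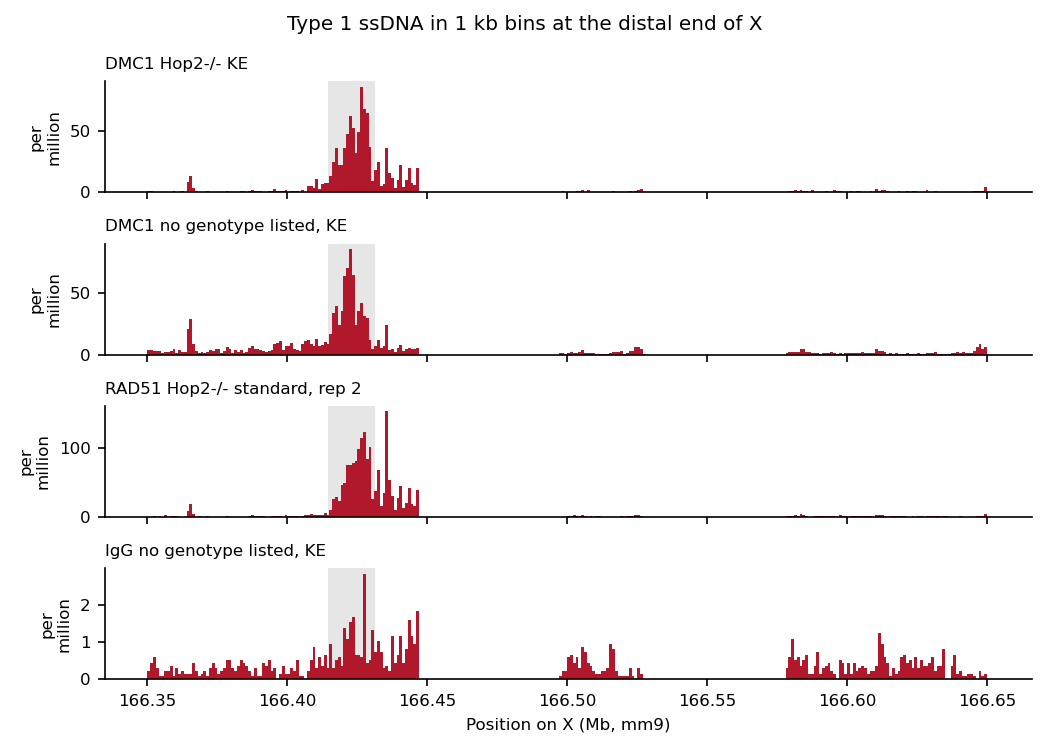
Type 1 ssDNA in FPM (vertical axes, each with its own scale) in 1 kb bins along the distal end of X (horizontal axis, Mb, mm9) in 4 libraries, with the called hotspot shaded. The hotspot stands out in all 3 antibody libraries (668 and 613 FPM over the shaded region in the KE libraries) and holds 15.4 FPM in IgG KE.

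Whether the hotspots are marked by ssDNA or by chromatin in general was examined by comparing classes within each library. The Hop2 -/- and IgG libraries were scored on the hotspots of unlabelled DMC1 KE, which covered 2.26% of the genome. The unlabelled DMC1 libraries were scored on those of Hop2 -/- DMC1 KE, which covered 2.53%. In Hop2 -/- DMC1 standard, 74.2% of type 1, 55.0% of type 2 and 3.19% of dsDNA fragments fell in hotspots. RAD51 gave 68.0% and 47.9% for type 1, with 2.86% and 2.85% for dsDNA. Unlabelled DMC1 standard gave 17.1% for type 1 and 2.81% for dsDNA. In KE, type 1 reached 45.8% (Hop2 -/-) and 26.03% (unlabelled), and the few dsDNA fragments reached 10.1% and 5.73%. Over the 8 DMC1 and RAD51 libraries the log2 ratio of the type 1 to the dsDNA share was 3.37 ± 0.99 (SD, n = 8), above 0 in 8 of 8 libraries (exact two-sided sign-flip permutation test, p = 0.00781, the smallest p possible). The Hop2 -/- IgG standard libraries had log2 ratios of 1.21 and 0.75, with 5.61% and 4.10% of type 1 in hotspots, and the IgG KE library -0.03, with 2.32%. IgG KE was also the control in calling, which removes windows where it is high, so its low values are partly set by the calling.

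**Figure D3:**
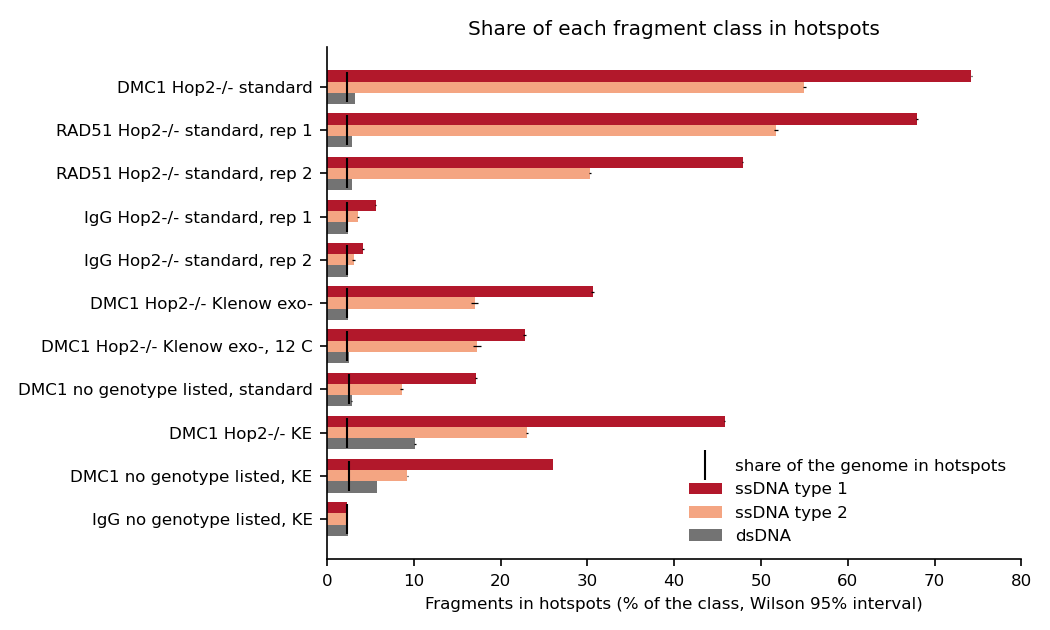
Share of type 1 ssDNA, type 2 ssDNA and dsDNA fragments that fall in hotspots (%, horizontal axis, bars with Wilson 95% intervals) in the 11 libraries, with the share of the genome in hotspots as a black tick. Type 1 reaches 74.2% in Hop2 -/- DMC1 standard and is 2.32% in IgG KE, near the 2.26% of the genome in hotspots. IgG KE was the control in calling these hotspots, which partly sets its low share.

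Resection leaves 3' ssDNA on opposite strands to the left and right of a break, so strand order around hotspot centres was measured. Within 2.5 kb of a centre, 86.4% ± 4.91 (SD, n = 8) of type 1 fragments in the DMC1 and RAD51 libraries lay left of the centre on the plus strand or right of it on the minus strand, above 50% in 8 of 8 libraries (exact two-sided sign-flip permutation test, p = 0.00781, the smallest possible). The values ranged from 80.01% in unlabelled DMC1 standard to 92.8% in RAD51 replicate 2. The Hop2 -/- IgG standard libraries gave 76.0% (75.5 to 76.6) and 68.7% (67.5 to 69.9). IgG KE gave 51.1% (50.9 to 51.3), and 49.8% when hotspots were called without the IgG control.

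**Figure D4:**
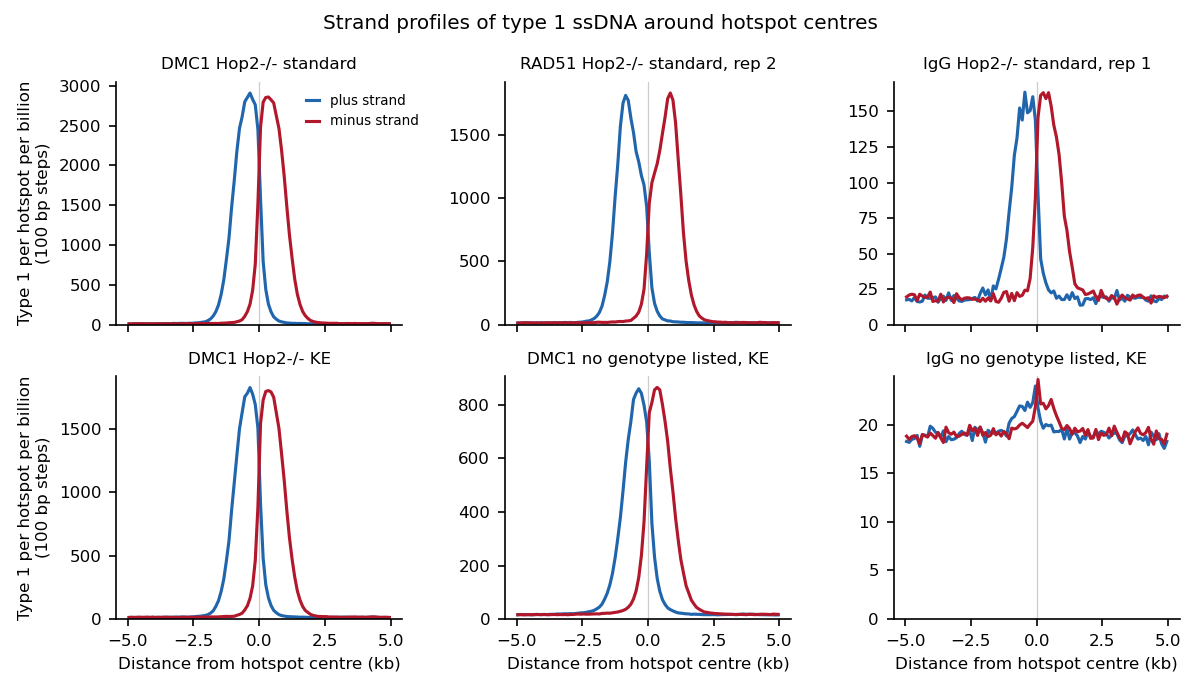
Type 1 ssDNA fragments per hotspot in 100 bp steps, in FPM times 1000 (vertical axes, each with its own scale) against distance from the hotspot centre (kb) in 6 libraries, plus strand in blue and minus strand in red. In Hop2 -/- DMC1 standard the plus strand peaks 350 bp left of the centre and the minus strand 350 bp right of it, in RAD51 replicate 2 both peaks lie at 850 bp, and the highest value in IgG KE is 24.6.

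RAD51 was compared with IgG at single hotspots, in the only pair of groups with 2 libraries each. Of the 10644 hotspots called in unlabelled DMC1 KE, 6945 were higher in RAD51 and 25 were lower (limma, Benjamini-Hochberg adjusted p below 0.05), and 9747 had a positive log2 fold. The median log2 fold was 2.38 with counts scaled to type 1 totals, and 4.61 with counts scaled to all fragments, a scaling under which 9921 hotspots were higher and 0 lower (limma; 0 lower also at an unadjusted p below 0.05, and 83 lower with voom weights and type 1 totals). The mean share of type 1 in hotspots was 57.9% ± 14.2 for RAD51 and 4.86% ± 1.07 for IgG (SD, n = 2 each). The depth of IgG limits these folds, because the median hotspot held 82 RAD51 and 2 IgG fragments over both libraries and 1647 hotspots held no IgG fragment. A pseudocount of 5 in place of 0.5 gave 1549 higher, a median log2 fold of 0.13 and 5653 positive folds. Leaving out RAD51 replicate 1 gave 3352 higher. The small count of lower hotspots moved with every library left out, to 6 and 4 without RAD51 replicates 1 and 2 and to 307 and 63 without IgG replicates 1 and 2, in fits that assume the lone library to vary like the other group.

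As both recombinases bind ssDNA at breaks, their strength and position were compared in Hop2 -/- standard libraries. Across the 10644 hotspots, which are not independent replicates, log2 FPM in RAD51 correlated with those in DMC1 at Pearson r = 0.974 (replicate 1) and 0.977 (replicate 2), and Spearman rho was 0.978 and 0.979. The RAD51 replicates correlated with each other at r = 0.974. With 765974 fragments in hotspots in each library, r was 0.960 and 0.955 against DMC1 and 0.961 between the replicates. The RAD51 fragments lay farther from the centres. The median distance from the centre was 505 bp in DMC1 and 595 and 735 bp in RAD51, a mean difference of 160 bp with a spread of 99.0 bp (SD, n = 2) between the RAD51 libraries. RAD51 replicate 2 came from the reciprocal cross, so the mean and the spread may include a difference between the crosses. The strand peaks lay 350 bp from the centre in DMC1, 550 bp in RAD51 replicate 1 and 850 bp in replicate 2. Both RAD51 libraries were above DMC1, which had 1 library, so no test was made. In the other DMC1 libraries the median distance was 495 bp (Hop2 -/- KE), 465 bp (unlabelled KE), 395 bp (unlabelled standard), 455 bp (Klenow exo(-), 12 °C) and 365 bp (Klenow exo(-)). Plus and minus strands differed by at most 10 bp in each of these libraries.

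Hotspot maps were compared between Hop2 -/- and unlabelled DMC1 after KE. Of the 11549 Hop2 -/- hotspots, 9788 (84.8%, Wilson 95% interval 84.1 to 85.4) overlapped an unlabelled hotspot by at least 1 bp, and 9801 of the 10644 unlabelled hotspots (92.1%, 91.6 to 92.6) overlapped a Hop2 -/- hotspot. Randomly placed intervals of the same lengths overlapped in 4.25% and 4.63% on average (highest of 100 draws, 4.64% and 5.21%). Both sets were called against the same IgG library, and how far this raises the overlap was not measured. Of 45 and 44 hotspots called in simulated libraries without hotspots, 32 were shared. Both simulated libraries were drawn from the same background, which favours shared calls, so they cannot measure it. Their calls were also few beside the 11549 and 10644 hotspots here. Hotspots found in 1 set were weaker than shared ones, with a median of 23.0 against 97.0 fragments in Hop2 -/- and 86.0 against 229 in the unlabelled set. Of the 1761 found only in Hop2 -/-, 1757 were autosomal. Of the 843 found only in the unlabelled set, 345 lay on X outside the distal 300 kb and 6 on Y. At 140000 fragments per library 29.3% of the Hop2 -/- and 79.6% of the unlabelled hotspots were shared.

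The X chromosome, which has no homologue along most of its length in males, differed between the Hop2 -/- and the unlabelled DMC1 libraries. On X outside its distal 300 kb lay 2.47% (exact binomial 95% interval 2.45 to 2.49) of hotspot type 1 fragments in Hop2 -/- DMC1 standard and 2.70% (2.67 to 2.72) in Hop2 -/- KE, against 14.4% (14.1 to 14.6) in unlabelled DMC1 standard and 13.8% (13.8 to 13.9) in unlabelled KE. The unlabelled share was 5.81 times that of Hop2 -/- by the standard protocol and 5.13 times by KE, or 7.74 times by KE with repeated fragments kept. RAD51 in Hop2 -/- gave 2.15% and 2.20%, the Hop2 -/- IgG libraries 2.83% and 3.52%, and IgG KE 4.04%. In the distal 300 kb of X the shares were 0.189% and 0.154% in Hop2 -/- DMC1 (standard and KE) and 0.291% and 0.286% in unlabelled DMC1, ratios of 1.54 and 1.86. On Y they were 0.00276% and 0.00883% against 0.0267% and 0.0446%. The Y shares were 0.0132% and 0.0146% in the Hop2 -/- IgG libraries (4 and 1 fragments) and 0.0332% in IgG KE. Among the DMC1 libraries named here only unlabelled KE exceeded IgG KE, so the Y difference is not clear of background. Counted over all type 1 fragments of the chromosome, without regard to hotspots, X held 2.96% and 3.36% in Hop2 -/- and 5.90% and 7.03% in unlabelled DMC1, ratios of 1.99 and 2.09. Per 1000000 type 1 fragments of the whole library, chrM held between 127 and 608 in the DMC1 and RAD51 libraries, and 1115, 4437 and 576 in the IgG libraries.

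**Figure D5:**
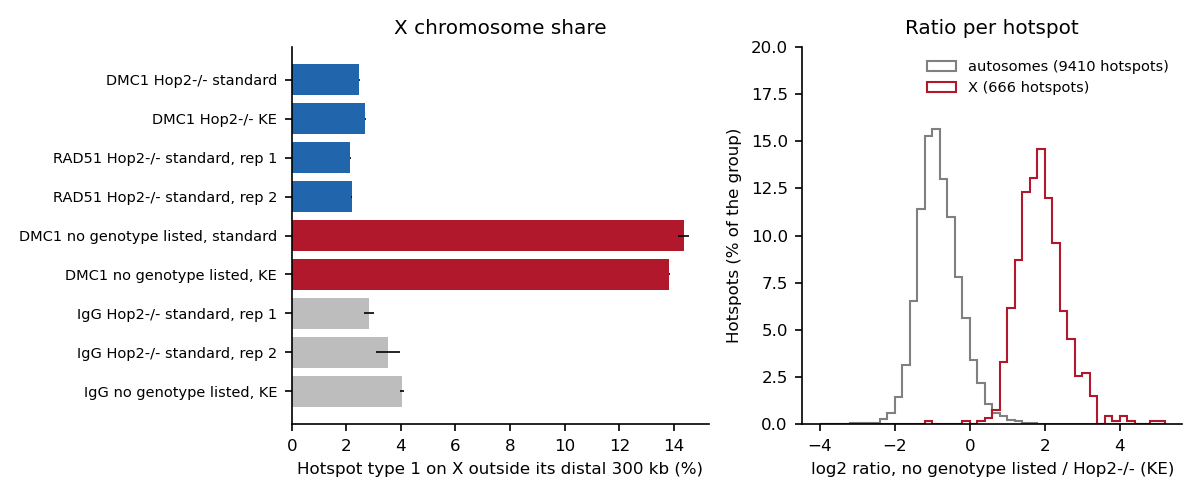
Left, share of hotspot type 1 fragments on X outside its distal 300 kb (%, horizontal axis) in 9 libraries, with exact binomial 95% intervals. Right, distribution of the log2 ratio of unlabelled to Hop2 -/- DMC1 KE per hotspot (horizontal axis) as a share of the autosomal or X hotspots (%, vertical axis), with medians of -0.86 for autosomal hotspots and 1.86 for X outside the distal 300 kb (the X curve includes 6 hotspots in the distal 300 kb).

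The same difference was seen hotspot by hotspot. Among hotspots with at least 100 fragments in the KE libraries together, the median log2 ratio of unlabelled to Hop2 -/- FPM was -0.86 on autosomes (9410 hotspots, quartiles -1.18 and -0.47) and 1.86 on X outside the distal 300 kb (660 hotspots, quartiles 1.49 and 2.28). Of these 660, 659 lay at least 2-fold above the autosomal median, as did 5 of 6 in the distal 300 kb and 4 of 4 on Y. On autosomes 525 lay at least 2-fold above the autosomal median and 183 at least 2-fold below it. FPM are scaled to all type 1 fragments, of which 26.7% lay in these hotspots in unlabelled KE and 47.2% in Hop2 -/- KE. A log2 ratio below 0 therefore need not mean a hotspot that is weak relative to the others of its library. The distal X hotspot described above had a ratio of -0.12 (exact 95% interval -0.19 to -0.06), or 0.34 with repeated fragments kept. Of the 10 highest ratios, 8 were on X, 1 on Y (258001 to 263000, 122 fragments in unlabelled KE and 1 in Hop2 -/- KE) and 1 on chromosome 11 (99292001 to 99298000, 171 and 2 fragments). All 10 rested on 4 or fewer Hop2 -/- KE fragments, so their log2 ratios are loose, 4.95 (exact 95% interval 2.45 to 10.27) for the Y site and 4.44 (2.57 to 7.50) for the chromosome 11 site. The chromosome 11 site held 29 fragments in Hop2 -/- DMC1 standard and 0 in unlabelled DMC1 standard, so the standard libraries did not show the same direction. Nor did they at the highest ratio, on X (12582001 to 12589000), with 6.40 FPM in Hop2 -/- and 3.23 in unlabelled DMC1 standard. The remaining sites went either way on few fragments. At the Y site the direction was the same, with 0.337 and 3.23 FPM, but these were only 1 and 2 fragments. IgG KE held 1.75 FPM at this site, above the 0.256 FPM of Hop2 -/- KE. Of the 10 lowest ratios, 7 lay between 123385001 and 124043000 on chromosome 9, with log2 ratios from -3.77 to -2.98. The lowest, on chromosome 13 (120275001 to 120282000), was -3.83 (-4.01 to -3.66), with 355 fragments in unlabelled and 1285 in Hop2 -/- KE, and 7 and 1175 by the standard protocol.

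KE was compared with the standard protocol in the same genotype label and antibody. The ssDNA share after KE was 5.12 times the standard share in Hop2 -/- DMC1, 16.2 times in unlabelled DMC1 and 19.3 times in IgG (against the mean of 2 standard libraries), where the standard libraries were Hop2 -/- and the KE library unlabelled. Fragments that were both type 1 and in hotspots went from 12.0% to 37.9% of the Hop2 -/- library, 3.15-fold, and from 0.804% to 18.7% of the unlabelled library, 23.3-fold. In the hotspots of both KE sets together, the share of type 1 fragments was lower after KE in Hop2 -/- (75.6% to 47.2%, ratio 0.624) and higher in unlabelled DMC1 (17.5% to 26.7%, ratio 1.53). In IgG it was 6.10% and 4.61% by the standard protocol and 2.79% by KE, where the KE library was the control in calling these hotspots.

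Finally, end repair by Klenow exo(-), which lacks the exonuclease activity that trims 3' ends, was compared with the standard end repair in Hop2 -/- DMC1. The ssDNA share was 9.24% after 1 h at 37 °C and 13.97% when 2 h at 20 °C and an overnight step at 12 °C followed, 0.495 and 0.748 times the standard 18.7%. Type 1 made up 87.0% and 88.3% of the ssDNA, against 87.2% in the standard library. The share of type 1 in hotspots fell from 74.2% in the standard library to 30.6% and 22.8%, ratios of 0.412 and 0.306, and strand order was 81.5% and 84.7% against 89.4%. The strand peaks lay 50 bp from the centre after 37 °C alone and 250 bp after the longer repair, against 350 bp. The median length of type 1 fragments was 86.0 and 76.0 bp against 84.0 bp. These are single libraries of 2768170 and 1973988 fragments, and the spread between preparations is unknown for them.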

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

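Of the tests in this part, the comparison of the RAD51 replicates and the ratios without fragments of score 0 were chosen only after the result was seen. The share of type 1 fragments in hotspots was lower after KE than by the standard protocol in the Hop2 -/- DMC1 libraries and higher in the unlabelled DMC1 libraries. The ratio of KE to standard was 0.624 in Hop2 -/- DMC1 and 1.53 in unlabelled DMC1, with 1 library on each side, and the difference was not tested.

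Removal of fragments with the same ends was examined first, because 17.1% of type 1 lines in Hop2 -/- KE and 42.2% in unlabelled KE were repeats. With repeats kept the ratios were 0.645 and 2.00, still on opposite sides of 1, which argues against it. Fragments with a score of 0, whose meaning is undocumented, were examined next. Without them the ratios were 0.631 and 1.51, which argues against these fragments as the cause. Spread between immunoprecipitations may account for part of the pattern. The share in hotspots differed between the RAD51 replicates by 0.50 on the log2 scale, against -0.68 and 0.61 for KE over standard, so with 1 replicate pair this cannot be told apart from an effect of KE. The RAD51 replicates came from reciprocal crosses, so their difference may hold more than the spread between immunoprecipitations. Genotype, which the labels give for the Hop2 -/- libraries alone, stays open as a biological explanation and was not tested.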

How the results depend on the processing

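The score above 0, unlabelled KE thinned to the depth of Hop2 -/- KE, the RAD51 to DMC1 correlation at equal depth, and the distance from centres without each RAD51 library were chosen only after the result was seen. Over 584 alternatives, values answering a comparison stayed within their spread in 122 and moved in 80. Values of single libraries or hotspots stayed in 197, moved in 183 and changed direction in 2. The cause of the moves below was not tested, except where fewer fragments or libraries are the alternative itself. Ratios are given as Hop2 -/- first and unlabelled second for KE over standard, and as 1 h first and 12 °C second for Klenow exo(-).

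Keeping repeated fragments gave 1091 hotspots in IgG KE, 82.9% of Hop2 -/- hotspots shared, r = 0.978 between RAD51 and DMC1, and X ratios of 7.74 (KE) and 6.80 (standard). KE over standard was 4.19 and 16.3 for the ssDNA share and 2.69 and 30.1 for type 1 in hotspots of all fragments. Klenow exo(-) over standard was 0.403 and 0.612 for the ssDNA share and 0.385 and 0.282 for type 1 in hotspots. The log2 ratio of the distal X hotspot changed direction, to 0.34.

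With type 2 added to type 1, 81.5% and 93.8% of Hop2 -/- and unlabelled hotspots were shared, r was 0.978, and the X ratios were 4.99 (KE) and 5.70 (standard). KE over standard for hotspots of all fragments was 3.04 in Hop2 -/-, Klenow exo(-) over standard for hotspots was 0.401 after 1 h, and 13 hotspots were lower in RAD51. With type 1 alone as ssDNA, KE over standard was 5.14, 15.3 and, in IgG, 18.3, and Klenow exo(-) at 12 °C was 0.758.

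Without the IgG control, IgG replicate 2 gave 20 hotspots, 91.0% of unlabelled hotspots were shared, r was 0.973, and the X ratios were 4.98 (KE) and 5.50 (standard). KE over standard for hotspots of all fragments was 3.19 and 22.1, Klenow exo(-) over standard for hotspots was 0.430 and 0.335, and 102 hotspots were lower in RAD51. Strand order in IgG KE fell to the other side of 50%, at 49.8%. An adjusted p of 1e-05 in calling gave 90.8% and 87.8% shared. The other hotspot set gave 3.19 and 23.6 for KE and 0.415 and 0.310 for Klenow exo(-). Subtracting the flank level gave X ratios of 5.48 (KE) and 6.47 (standard), and all type 1 on X gave 2.09 and 1.99.

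With a score above 0, IgG replicate 2 gave 5 hotspots. KE over standard was 4.77 and 15.3 for the ssDNA share and 2.99 and 21.9 for hotspots of all fragments. Klenow exo(-) was 0.490 and 0.730 for the ssDNA share and 0.423 and 0.317 for hotspots.

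Depth limits the number of hotspots. Thinned to 140000 type 1 fragments, Hop2 -/- DMC1 standard gave 3211, RAD51 2811 and 2091, Klenow exo(-) 1232 and 838, unlabelled DMC1 standard 366, Hop2 -/- KE 2118 and unlabelled KE 776. IgG replicate 1 gave 5 and IgG KE 9. The shared percentages were then 29.3% and 79.6%. With unlabelled KE thinned only to the depth of Hop2 -/- KE they were 83.2% and 90.9%. At equal depth the mean r between RAD51 and DMC1 was 0.957.

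For RAD51 against IgG, a pseudocount of 5 gave 1549 higher and 0 lower (limma, with 71 lower at an unadjusted p below 0.05). Scaled to all fragments 0 were lower (limma, 0 at an unadjusted p below 0.05), at least 10 fragments over the 4 libraries gave 9 lower, and voom weights 83. Leaving out each library in turn gave 3352 to 8448 higher and 4 to 307 lower.

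With the replicate number as a block, 6058 hotspots were higher and 13 lower, against 6945 and 25 without the block. The numbers mark the direction of the cross and do not establish shared animals. The deviations of RAD51 and IgG replicate 1 from their group means correlated at 0.0816 across hotspots. With 2 libraries per group, those of replicate 2 are their mirror image and add nothing. The median hotspot held 2 IgG fragments over both libraries, so counting error would hide a shared deviation. This value therefore cannot tell whether the libraries are paired, and the main fit used no pairing.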

Other observations

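All tests in this part were chosen only after the result was seen. Identical type 1 fragments, with the same ends and strand, recurred between separately made libraries. Of 27832 and 27783 hotspot fragments drawn from the RAD51 libraries, 39.4% and 39.7% were present in Hop2 -/- DMC1 standard, against 9.57% of 27202 and 7.96% of 27531 in the Klenow exo(-) libraries. Shifted by 25 bp, between 0.121% and 0.182% of fragments matched Hop2 -/- DMC1 standard in the RAD51, IgG replicate 1 and Klenow exo(-) libraries.

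Autosomal hotspots near the distal chromosome end had lower ratios of unlabelled to Hop2 -/- DMC1 KE than those farther away. The median log2 ratio was -1.47 within 0.5 Mb of the end (36 hotspots) and -1.53 between 0.5 and 1 Mb. It was -1.17 between 2 and 5 Mb, -1.02 between 20 and 50 Mb and -0.73 beyond 50 Mb (5573 hotspots). These medians pool the hotspots of all autosomes, which differ in length. They cannot tell a decline along each chromosome from a difference between chromosomes, so contrasts within chromosomes were made for the distal part. Over 19 autosomes the last 5 Mb (405 hotspots) differed from the rest by -0.35 ± 0.38 (SD, n = 19), below 0 in 15 of 19 (two-sided permutation test by sign flips, p = 0.00129). The last 2 Mb differed by -0.54, below 0 in 16 of 18 autosomes (permutation p = 6e-05), and the last 10 Mb by -0.32, below 0 in 19 of 19 (permutation p = 1e-05, the smallest that 100000 sign flips can give). Each side was 1 library, so the permutation p-values for this pattern measure agreement between chromosomes, not spread between preparations or mice.

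The tables argue against 4 technical explanations as the whole cause of this distal pattern. With background fragments between hotspots subtracted the difference was -0.39 (permutation p = 0.00057), with the dsDNA ratio of the standard libraries around each hotspot subtracted, as a measure of copy number, -0.30 (p = 0.00059), and without chromosome 9 -0.32 (p = 0.00234). For regional coverage of the KE libraries, KE type 1 fragments outside hotspots within 25 kb were used, which differed themselves by -0.11 (permutation p = 0.0062), and subtracting their ratio left -0.22, below 0 in 16 of 19 autosomes (permutation p = 0.00272), so coverage can account for part of the difference. In the standard libraries, also with the background between hotspots subtracted, it was -0.30, below 0 in 15 of 19 autosomes (permutation p = 0.02214), so a difference of the mice seen in both protocols is a candidate explanation. Genotype, another property of the mice and differences between single preparations cannot be separated with these libraries.

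The Hop2 -/- IgG standard libraries carried hotspot signal. In the 1065 hotspots strongest in RAD51, type 1 fragments were 6.86 and 4.48 times as dense as the length of the hotspots gives, against 0.995 and 1.09 times in the 1064 weakest. Mapping or sequence properties of the regions alone are argued against by the strand order of IgG KE, 51.1% against 76.0% and 68.7%, and by dsDNA of IgG replicate 1, of which 2.43% fell in hotspots against 5.61% of type 1 (2.44% against 4.10% in replicate 2). Carry-over of molecules from another library could also give such signal. As counted, 27.8% and 23.9% of hotspot fragments of IgG replicates 1 and 2 were identical to fragments of Hop2 -/- DMC1 standard, against 39.4% and 39.7% for RAD51. Estimated background made up 38.8% and 54.0% of these IgG fragments, and 1.09% and 2.51% of the RAD51 fragments. With it removed at the match rate of IgG KE, the shares were 42.3% and 46.1% for IgG and 39.8% and 40.6% for RAD51. For the other DMC1 libraries they were between 8.22% and 35.2%. The IgG shares thus rest on the size of this correction. Within Hop2 -/- DMC1 standard the share was 44.7%, without removal of its background, which was 0.801% of its hotspot fragments. Carry-over from it cannot be told apart from binding of ssDNA in the IgG preparation, because the RAD51 libraries, made separately by the same protocol, share nearly as many fragments as parts of that library do. For RAD51 replicate 2 the shares were 29.7% and 36.2% against 31.6% for RAD51 replicate 1 and, without removal of a background of 2.51%, 41.1% within that library, which argues against carry-over from it in IgG replicate 1 and leaves it open in IgG replicate 2, where 6093 fragments were drawn. No biological explanation was tested.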
